A study of Mus musculus with 4 samples.

How the data were processed

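Peripheral CD8+ T cells of wild-type (WT) C57BL/6 mice and of µMT mice, which lack mature B cells because of a targeted deletion in the gene of the immunoglobulin µ heavy chain (Ighm), had been measured by droplet sequencing of single cells. Per the labels, the cells were purified by magnetic separation and stained with oligonucleotide-tagged antibodies to CD44, a receptor that is high on memory and activated T cells, and to CD62L, the lymph node homing receptor of naive and central memory T cells. Each genotype gave 1 mRNA library (10x Genomics chemistry that reads the 3′ end of transcripts) and 1 antibody tag library of the same cells, so the series holds 4 libraries. The labels state a target of 3000 cells per genotype and 100000 read pairs per cell, with mRNA and antibody libraries pooled 9 to 1. How many animals gave the cells is not stated, and there were no replicates.

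The deposited mRNA tables hold counts, the number of unique molecular identifiers (UMIs) per gene and cell barcode, without normalization. The deposited antibody tables hold counts of tags per antibody and cell barcode, also without normalization. The submitters' processing notes name Cell Ranger 3.0.2 and the mouse genome build mm10. The annotation release, the settings that separated cells from empty droplets and any collapsing of duplicate antibody tags are not stated. The antibody tables hold 3 antibodies, although the labels name 2: the additional antibody is Sca1, the product of Ly6a. The 31053 gene identifiers were matched to symbols and coordinates of GENCODE mouse release 21, which is built on the same genome; 30934 matched and 56 share a symbol with another identifier. Tags of near-identical genes, such as Hspa1a and Hspa1b, cannot always be assigned to 1 copy, and a 3′ tag does not show which exons a transcript holds.

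Barcodes present in the mRNA and antibody tables of a genotype were kept if they had at least 500 detected genes and at most 10% of UMIs from mitochondrially encoded genes. A cell was called CD8-positive with at least 1 UMI of Cd8a or Cd8b1, at least 1 UMI of Cd3e, Cd3d or Cd3g, no Cd4 UMI, at most 1 UMI over Cd79a, Cd79b and Ms4a1, and at most 1 UMI over Lyz2, Csf1r and Csf3r. For each antibody and library, log10(count + 1) of these cells was fitted with a mixture of 2 Gaussians (scikit-learn 1.9.0), and the threshold was the point between the means where both were equally probable. The thresholds divide the cells into 4 gates: CD44low CD62Lhigh, CD44low CD62Llow, CD44high CD62Lhigh and CD44high CD62Llow. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals.

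For gene comparisons the UMIs of all cells of a group were summed per library and given relative to all UMIs of the sum (CPM) with exact Poisson 95% intervals. A gene was called higher or lower by a size rule: at least 1.5-fold apart, at least 20 CPM in 1 library or more, at least 30 UMIs over both sums, and intervals that do not overlap. A sum without UMIs was set to the limit that 3 counts allow. With 1 library per genotype no test of the genotype was possible, and cells are not replicates of a genotype. All intervals cover counting error only and not variation between animals, stainings or library preparations. A gate with under 50 cells in a library received no gene comparison. The same rule compared CD44low CD62Llow with CD44low CD62Lhigh cells within each library.

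There were 17 gene lists: naive and quiescence, immediate-early and TCR-induced, cytotoxic and effector, memory, type I interferon response, gut homing and tissue residency, inhibitory receptors and exhaustion, mitochondrially encoded, nuclear oxidative phosphorylation, glycolysis, oxidative stress defence, cell cycle, cytosolic ribosomal proteins, heat shock and handling stress, survival and apoptosis, the group of costimulation, TCR complex and CD8, and the group of TGF-beta and retinoid response. For each, the median log2 fold of the members with at least 20 CPM was placed among 10000 random lists of as many genes, matched on expression in 20 bins. Its interval comes from 500 Poisson draws of the counts. Neither the percentile nor the interval tests the genotype. Ly6a is a member of both the memory and the interferon lists, and Crip1 and Id2 are in the memory list.

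The genes named were, for all CD8-positive cells, the 12 highest and the 12 lowest folds among those called, and for each gate the 8 highest and 8 lowest. Immunoglobulin, TCR V, D and J and ribosomal protein genes and the sex-linked genes Xist, Ddx3y, Uty, Kdm5d and Eif2s3y were left out of this choice; other genes on the sex chromosomes were not. For the comparison of the CD62Llow with the CD62Lhigh gate, they were up to 12 each way called in both libraries, ordered by the smaller fold. Each list gave up to 4 members by the size of the fold, and Cd44, Cd8a, Cd8b1 and Ighm were always included; results of further genes that had been planned are not reported here, and any other gene named was chosen after its values were seen. Gate definitions, filters, size rule, lists, this rule and the alternatives were fixed before the data were examined, except the alternatives said to have been added.

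To compare lists per cell at the same depth, each cell was thinned to 7224 UMIs and cells with fewer were left out. For clusters, cells passing the gene and mitochondrial filters were scaled to 10000 UMIs, log-transformed and reduced to 2000 variable genes, 30 principal components and 15 neighbours (scanpy 1.11.5), and grouped by the Leiden method (igraph 0.11.9) at resolution 0.6, without joining the libraries. TMM scaling factors were 1.03 for WT and 0.971 for µMT and were checked against edgeR 4.0.16. Other values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The size rule and the list percentiles were tested on simulated Poisson counts, and the threshold method on simulated Gaussians. These simulations held no variation between cells, animals or preparations. None was set to the depth of the WT CD44low CD62Llow cells, so they do not show how the rule behaves beyond counting error.

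The alternatives were thresholds from pooled cells, from pooled cells after aligning the density peaks, and 0.1 higher or lower on the log10 scale; leaving out cells within 0.1 of a threshold; no CD8 gate; at least 1000 genes and at most 5% mitochondrial UMIs; removal of cells called doublets by Scrublet; TMM scaling; totals without mitochondrial and ribosomal protein genes; a minimum of 50 CPM or none; a 2-fold rule; equal weight for each cell; gate shares set equal in both libraries; and cluster resolutions of 0.4 and 1.0. Chosen after seeing the data were a CD44 threshold of 1000 tags, the removal of cells under 3000 UMIs, and the removal of genes with over 25% of their UMIs in 1 cell.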

Results

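The mRNA tables held 2446 WT and 2566 µMT barcodes with 24338717 and 26018367 UMIs. After the filters 2199 WT and 2450 µMT cells were left, of which 2116 (96.2%) and 2380 (97.1%) were called CD8-positive. These cells had a median of 10420 UMIs in WT (range 724 to 64090) and 10003 in µMT (range 778 to 50323), and medians of 2549.5 and 2424.5 detected genes. The mitochondrial share had a median of 6.04% in WT and 5.89% in µMT. In the summed cells, 3 counts correspond to 0.131 CPM in WT and 0.120 CPM in µMT.

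Ighm, the gene targeted in µMT mice (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730 on the minus strand of mm10), was counted at 277 CPM in all WT barcodes and 187 CPM in all µMT barcodes. In CD8-positive cells its log2 fold was -0.57, under the size rule; by gate it was called lower in CD44high CD62Lhigh (-0.60) and CD44high CD62Llow cells (-0.68) and not called in the others. A 3′ tag outside the deleted part of the gene checks nothing about the deletion. Over all barcodes Igkc, the kappa light chain constant gene, had 3 UMIs in WT and none in µMT, where a count of 0 allows up to 0.115 CPM. Ms4a1 had 1 UMI in each library, the myeloid gene Lyz2 none in either, and Cd4 2 UMIs in WT and none in µMT. Cd79b, a B cell receptor component, was at 22.2 CPM in WT and 16.2 CPM in µMT. Xist was at 713 and 677 CPM, and the Y-linked Ddx3y had no UMI in either library.

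The first comparison asked how naive-like and memory-like surface phenotypes are distributed in mice with and without B cells. Cells with low CD62L made up a larger share in µMT than in WT. CD44high CD62Llow cells, a surface phenotype often called effector memory, were 63 of 2116 (2.98%, 2.30 to 3.79%) in WT and 131 of 2380 (5.50%, 4.62 to 6.50%) in µMT, 1.85 times the WT share. By mRNA, only 12 of the WT and 14 of the µMT cells of this gate lay in the memory-like cluster described below, and with a CD44 threshold of 1000 tags, added after seeing the data, the gate held 17 (0.803%, 0.469 to 1.28%) and 30 (1.26%, 0.852 to 1.79%), a difference of 0.457 points. CD44low CD62Llow cells were 100 (4.73%, 3.86 to 5.72%) in WT and 147 (6.18%, 5.24 to 7.22%) in µMT, a difference of 1.45 points (0.0879 to 2.81). All CD62Llow cells together were 163 (7.70%) and 278 (11.7%), a difference of 3.98 points (2.22 to 5.73). The direction was not kept with at least 1000 genes and at most 5% mitochondrial UMIs, which left 253 WT and 406 µMT cells: the differences were then -1.27 points for CD44low CD62Llow and -1.16 for CD44high CD62Llow cells.

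CD44low CD62Lhigh cells, the naive phenotype, were 902 (42.6%, 40.5 to 44.8%) in WT and 847 (35.6%, 33.7 to 37.5%) in µMT. CD44high CD62Lhigh cells were 1051 (49.7%, 47.5 to 51.8%) and 1255 (52.7%, 50.7 to 54.8%). By mRNA, only 169 of the WT and 205 of the µMT cells of this gate lay in the memory-like cluster described below. Another 734 WT and 824 µMT cells lay in the largest cluster of their own library, as did most CD44low CD62Lhigh cells. The CD44 thresholds were 102 tags in WT and 73.1 in µMT, and those of CD62L were 273 and 267 tags. The split by CD44 depended on these thresholds: from pooled cells, CD44high CD62Lhigh cells differed by -1.25 points in place of 3.06, and after aligning the peaks by -4.06 points. With the CD44 threshold of 1000 tags CD44high cells of either CD62L level were 309 (14.6%) in WT and 365 (15.3%) in µMT.

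The mRNA followed the CD44 tags. Cd44 mRNA was at 1.45 CPM in WT and 0.880 CPM in µMT CD44low CD62Lhigh cells, against 27.6 and 28.7 CPM in CD44high CD62Lhigh cells. Ccl5, a chemokine stored by memory CD8+ T cells, was at 10.1 CPM in WT cells with 100 to 300 CD44 tags and at 592 CPM in those with 1000 to 3000 tags. The WT CD44low CD62Llow cells were shallow, with a median of 3138.5 UMIs against 7682 in µMT, and 48.0% of them had under 3000 UMIs. Without cells under 3000 UMIs, left out after seeing the data, the gate held 52 (2.52%) WT and 124 (5.29%) µMT cells.

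**Figure D1:**
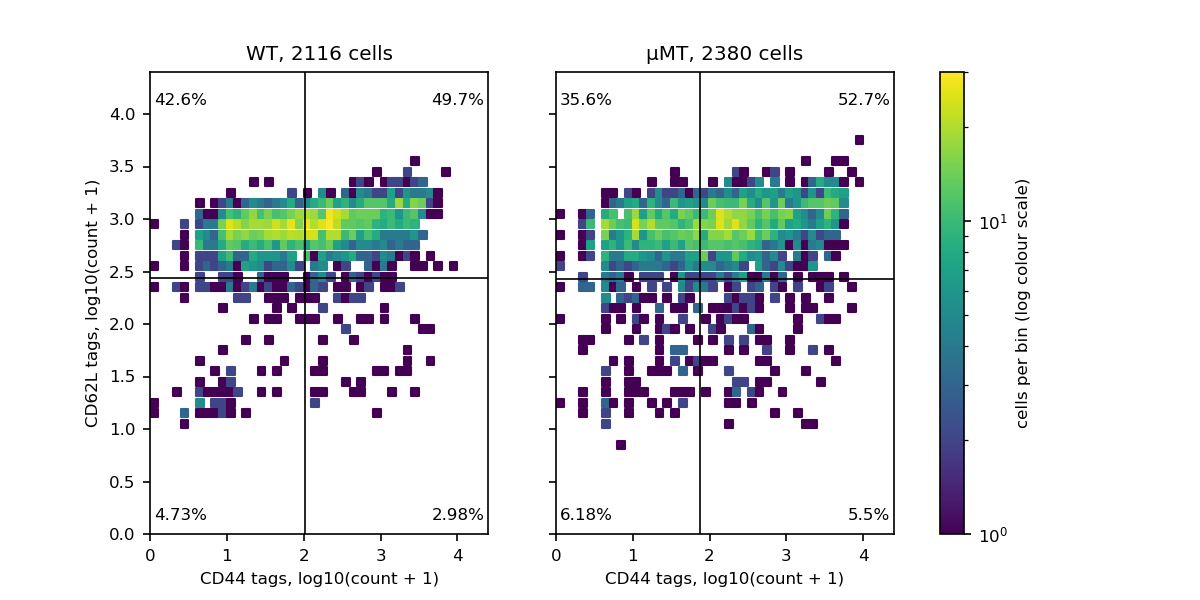
CD44 tags (x axis) and CD62L tags (y axis), both as log10(count + 1), in CD8-positive cells of WT (left) and µMT (right); colour gives the number of cells per bin on a log scale, lines the thresholds and corner values the share of cells per gate. The lower right gate holds 2.98% of WT and 5.50% of µMT cells.

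The next comparison asked how CD8+ T cells of µMT mice differ from those of WT mice in their mRNA. The lists of immediate-early and TCR-induced genes and of heat shock genes had medians above those of random lists. Hspa1b, an inducible heat shock chaperone, had the highest fold at 2.18 CPM in WT (1.62 to 2.88) and 25 CPM in µMT (23.1 to 27.1), a log2 fold of 3.52; its neighbour Hspa1a is nearly identical, so the copy is uncertain. Irs2, an adaptor of insulin and cytokine receptors, was at 9.21 and 40.1 CPM (log2 2.12). The lowest was Crip1, a small LIM-domain protein, at 618 CPM in WT (608 to 628) and 209.8 CPM in µMT (204 to 215.5), a log2 fold of -1.56.

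Of 4850 genes over the minimum, 110 were higher and 37 lower in µMT, and the median log2 fold of all genes was -0.07. With TMM scaling, which moved this median to 0.01, 135 were higher and 21 lower. More genes were higher than lower in every other setting except no CPM minimum, with 314 and 319, and at least 1000 genes and at most 5% mitochondrial UMIs, with 131 and 131. The other genes with the highest folds were the small GTPase Rhob (log2 1.99), the transcription factor Klf9 (1.72), the ERK phosphatase Dusp5 (1.66), the vesicle sorting gene Vps37b (1.66), the endoplasmic reticulum chaperone Dnajb9 (1.65), the G protein regulator Rgs2 (1.62), the MAP kinase phosphatase Dusp1 (1.62), the NF-κB inhibitor Tnfaip3 (1.62), the stress gene Gadd45b (1.60) and Tagap (1.60). Below Crip1 stood Gm47283 (-1.05), Stmn1 (-1.02), AI467606 (-0.92), the linker histone gene Hist1h1e (-0.86), Tspan32 (-0.81), Slc14a1 (-0.80), the chemokine receptor Cxcr3 (-0.79), Ccdc85b (-0.78), Cd160 (-0.77), Mir142hg (-0.77) and Ddit4 (-0.77). Gm47283 is annotated on the Y chromosome, but Ddx3y had no UMI in either library; it has near-identical copies, so the origin of its UMIs and its fold are uncertain, and 14.3% of the Stmn1 UMIs came from 1 cell.

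**Figure D2:**
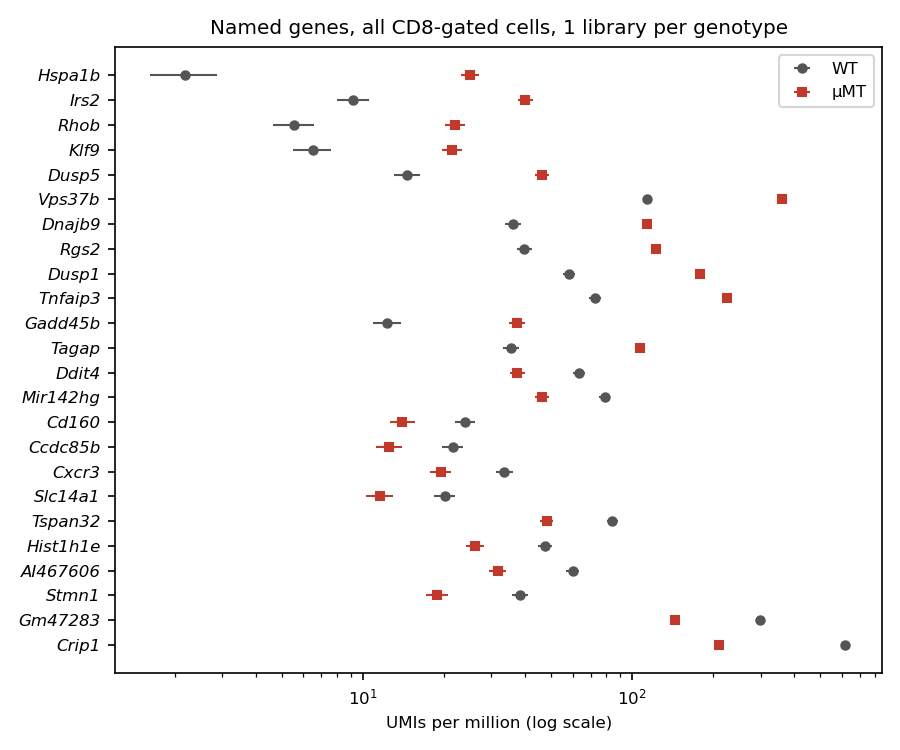
CPM (x axis, log scale) of the 24 genes named by size of fold in all CD8-positive cells of WT (circles) and µMT (squares), 1 library each, with 95% Poisson intervals. Hspa1b was at 2.18 CPM in WT and 25 CPM in µMT, and Crip1 at 618 and 209.8 CPM.

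Of the 24 immediate-early and TCR-induced genes over the minimum, 15 were higher and none lower, with a median log2 fold of 0.79 (0.73 to 0.84), above all random lists (percentile 100). Besides Dusp5, Dusp1 and Tnfaip3 they included the orphan nuclear receptor Nr4a2 (1.47). Of 10 heat shock and handling stress genes, 4 were higher: Hspa1b, Dnajb1 (0.78), Hsp90aa1 (0.75) and Hspa5 (0.64), with a list median of 0.40 (percentile 100). In cells thinned to 7224 UMIs, with 198 WT and 238 µMT cells left out, the median number of UMIs from the immediate-early list was 26 in WT and 45 in µMT, against 41 and 66 before thinning. The quartiles after thinning were 20 to 34 in WT and 35.25 to 56 in µMT. Heat shock UMIs had medians of 30 and 38 after thinning and 45 and 55 before.

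The cytosolic ribosomal protein list was placed at percentile 99.7 with a median of 0.06 and no gene called out of 83. Its largest folds were those of Rps27l (-0.42), Rpl7l1 (-0.27), Rps19bp1 (-0.24) and Rpl35 (-0.19), all opposite in sign to the list median. Members were taken by the symbol prefixes Rpl and Rps, so not all are ribosomal proteins: Rps19bp1 is a binding protein. Nuclear oxidative phosphorylation genes had a median of -0.13 (percentile 0.210), with none of 82 called. Ndufaf3 was at -0.35, and Ndufa5, Ndufs4 and Ndufa3 at -0.29, -0.29 and -0.28. The 13 mitochondrially encoded genes had a median of -0.02 (percentile 31.8), which was 0.06 with TMM scaling, and none was called.

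Costimulation, TCR complex and CD8 genes had a median of -0.14 (percentile 1.09): Icos (1.17) and Cd28 (0.96), costimulatory receptors, were higher, Cd27 (-0.70) was lower, and the other 16 of 19 were not called. Lck was at -0.40, Cd8a at -0.38 and Cd8b1 at -0.24. The naive and quiescence list had a median of -0.02 (percentile 82.0; 0.07 with TMM scaling). Of its 21 genes Klf2 (0.65), a regulator of lymphocyte egress, was higher; Il7r was at 0.56, Ccr7 at 0.44 and Ccr9 at -0.29. Cd44 was at 0.15. Of 17 memory genes Ly6a (0.82) was higher and Crip1 and Cxcr3 were lower, with a median of 0.03 (percentile 95.8). Lgals1 was at -0.44.

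Of 35 type I interferon response genes, 3 were higher, Ifit3 (0.84), Ly6a and Ifit1 (0.62); Isg15 was at 0.54. The median was -0.07 (percentile 53.7) and 0.03 with TMM scaling. Gut homing and tissue residency genes (12 over the minimum) had a median of -0.05 (percentile 68.4) and 0.03 with TMM scaling; Rgs2, Rgs1 (1.26) and Cd69 (0.78) were among the 4 higher, and Cd160 was among the 2 lower. Of 4 inhibitory receptor and exhaustion genes, the checkpoint receptor Ctla4 (1.51) was higher, Cd160 lower, Izumo1r at 0.09 and Tox at -0.05, with a median of 0.02 (percentile 81.5).

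None of the 6 cytotoxic and effector genes was called (median -0.17, percentile 5.92); Id2 was at 0.34, Ccl5 at -0.27, Ctsw at -0.22 and Nkg7 at -0.21. None of 13 glycolysis genes (median -0.12, percentile 16.7), 19 oxidative stress defence genes (-0.10, percentile 28.8) or 9 survival and apoptosis genes (0.06, percentile 95.8) was called. Slc16a1 was at 0.55, Eno1 at -0.41, Keap1 at -0.47, Sod1 at 0.42, Bbc3 at 0.55 and Casp8 at -0.45. Of 12 cell cycle genes Cks2 (0.71) was higher and Stmn1 lower (median -0.13, percentile 17.2), with Cenpa at 0.50. Of 9 TGF-beta and retinoid response genes the repressor Tgif1 (1.40) was higher, Skil was at 0.46 and Smad7 at 0.30 (median 0.03, percentile 88.9).

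**Figure D3:**
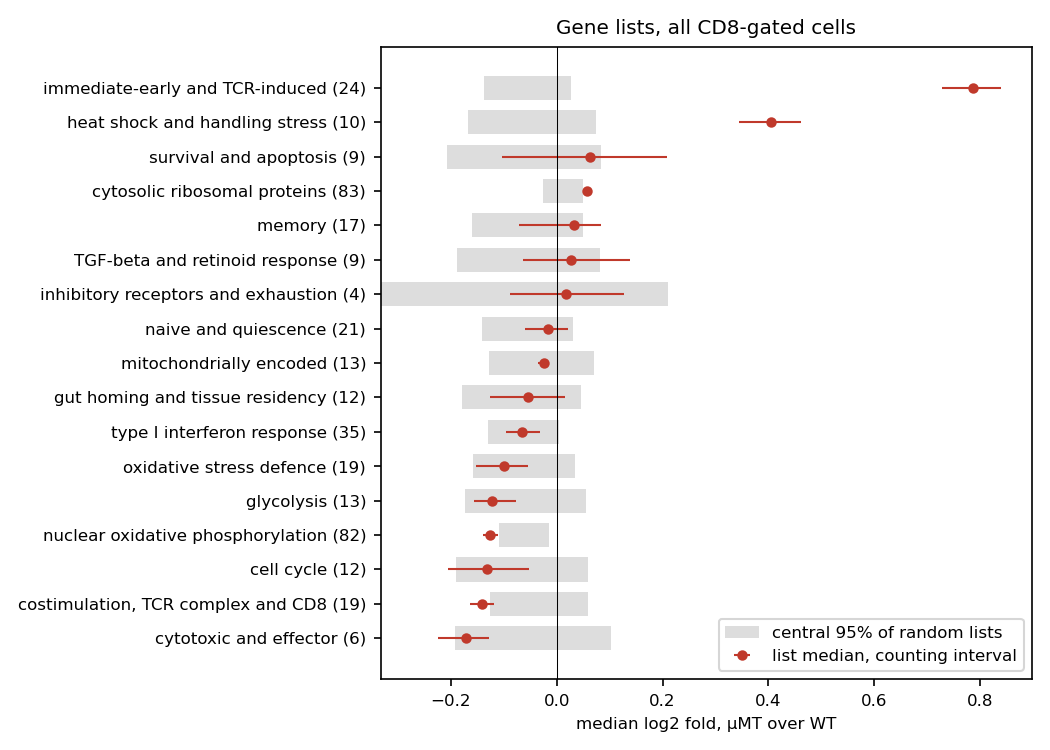
Median log2 fold of µMT over WT (x axis) of the 17 gene lists in all CD8-positive cells (points, with Poisson 95% intervals; members over the minimum in parentheses) and the central 95% of random lists matched on expression (grey bars). The immediate-early list at 0.79 and the heat shock list at 0.40 lie to the right of their bars.

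The next comparison was between genotypes within each gate, and asked whether the folds were found in cells of the same surface phenotype. The immediate-early list had medians of 0.78 in CD44low CD62Lhigh, 0.74 in CD44low CD62Llow, 0.80 in CD44high CD62Lhigh and 0.98 in CD44high CD62Llow cells, each at percentile 100. Called higher were 14 of 24, 12 of 25, 15 of 24 and 17 of 25 of its genes in the same order, and 2 were lower, both in CD44high CD62Llow cells. The heat shock list had medians of 0.44, 0.65, 0.35 and 0.12, at percentiles 100, 100, 99.99 and 95.9. In all 4 gates 30 genes were higher in µMT, among them Fos, Fosb, Jun, Junb, Dusp1, Cd69, Klf2, Irs2 and Hspa1b. Another 4 were lower in every gate: Crip1, Gm47283, Tspan32 and the chemokine receptor Cxcr6.

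In CD44low CD62Lhigh cells 125 genes were higher and 59 lower. Ctla4 was at 4.47 CPM in WT and 21.4 CPM in µMT (log2 2.26), followed by Irs2 (2.23), Dusp5 (2.03), Nr4a2 (1.96) and Gadd45a (1.84). Crip1 was at 566 and 189 CPM (log2 -1.58), and Cxcr6 at -0.85. In CD44high CD62Lhigh cells 112 genes were higher and 54 lower, with Klf9 (2.06) and Irs2 (2.03) below Hspa1b (3.88), and with Cxcr3 (-0.88) and Tspan32 (-0.85) lower. The gates CD44low CD62Lhigh and CD44high CD62Lhigh shared 96 higher genes of 4698 over the minimum in both, where independent lists would share 2.76. Both gates come from the same WT and µMT libraries, so any difference between these libraries can appear in both. The lists are therefore not independent, and the sharing is no replication. The memory list medians of these gates were -0.04 (percentile 66.9) and -0.20 (percentile 0.330).

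In CD44low CD62Llow cells 74 genes were higher and 53 lower. These 127 became 207 with the CD44 threshold of 1000 tags. With each cell weighted equally they became 621, but the intervals are then too narrow. Interferon response genes had a median of 0.18 (percentile 99.97), with Ly6a at 15.4 CPM in WT and 77.6 CPM in µMT (log2 2.34), Ifit1 at 1.87 and Isg15 at 1.44. The memory list had a median of -0.31 (percentile 0.650), with Lgals1, a galectin of activated T cells, at 162 and 52.7 CPM (log2 -1.62). The smaller depth of the WT cells in this gate is given above.

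In CD44high CD62Llow cells 97 genes were higher and 243 lower, and 74 of these had over 25% of their UMIs in 1 cell; without them 94 were higher and 172 lower. The cell cycle list had a median of -3.35 with 22 of 30 genes lower, but 84.1% of the Mki67 UMIs and 72.2% of the Pclaf UMIs came from 1 cell. Ccl5 was at 916 CPM in WT and 53.0 CPM in µMT (log2 -4.11), with 45.6% of its UMIs in 1 cell. The naive list had a median of 0.34 with 6 of 21 genes higher, among them Klf2 (1.06) and Il7r (0.73). The cells of this gate were of mixed kinds: the memory-like cluster held 12 of the 63 WT and 14 of the 131 µMT cells, and the cycling cluster 8 and 10, which bears on all of these folds. S100a4, with 1 UMI in WT, had a log2 fold of 5.32 (2.80 to 10.65), and 98.7% of its UMIs were in 1 cell.

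The last comparison asked what sets CD44low CD62Llow cells, which were low for both antibodies, apart from CD44low CD62Lhigh cells of the same library. In WT their median of Sca1 tags was also lower, 11.5 against 28, as was that of UMIs, 3138.5 against 9782.5. In µMT these medians were 180 against 260 tags and 7682 against 9298 UMIs. Whether these cells had lost the homing receptor or gave fewer tags in general was not tested. Few genes differed in both libraries. Higher in both were Elovl1, a fatty acid elongase (log2 1.03 in WT and 0.97 in µMT), Ttc38 (1.38 and 0.95) and the immediate-early gene Fosb (0.79 and 1.42). Lower in both were Olfr1369-ps1 (-4.74, interval -10.04 to -2.25, and -1.78), the ferredoxin Fdx1 (-2.54, interval -5.59 to -0.67, and -0.96) and the phosphatase Dusp7 (-1.62 and -0.92). All 6 WT folds rested on few UMIs in the CD62Llow cells. Elovl1 had 18 (interval of the fold 0.24 to 1.73), Ttc38 16 (0.52 to 2.13) and Fosb 30 (0.20 to 1.33). Olfr1369-ps1 had 1, Fdx1 2 and Dusp7 5 (-3.25 to -0.38).

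In WT 96 genes were higher and 39 lower in the CD62Llow cells, and in µMT 45 were higher and 16 lower. Independent lists would share 0.931 higher and 0.134 lower genes. No gene was called in opposite directions, but the number that independent lists would give was not computed, so this shows no agreement. Interferon response genes had a median of 0.24 in µMT (percentile 100), with Isg15 at 0.89, and of 0.01 in WT (percentile 26.7), with Ifit1 at -1.21. The memory list had a median of 0.23 in WT (percentile 99.5), with Lgals1 at 1.02 and the scaffold gene Ahnak at 1.01, and of -0.04 in µMT (percentile 8.43). In WT the naive list was also above random lists (0.16, percentile 99.5), as were the costimulation list (0.11, percentile 99.2) and the immediate-early list (0.18, percentile 98.3), and mitochondrially encoded genes were below (-0.11, percentile 0.0100), in a gate whose WT cells were shallow. The costimulation list was above random lists in µMT too (0.07, percentile 97.9). The heat shock list was at -0.10 in WT and 0.25 in µMT. The difference between the libraries was not tested. In place of 3 genes higher in both there were 0 with TMM scaling or a 2-fold rule. With each cell weighted equally there were 59, but the intervals are then too narrow. In place of 3 lower there were 0 with a minimum of 50 CPM or the CD44 threshold of 1000 tags.

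The 4649 cells that passed the filters fell into 7 transcriptome clusters. The largest pair were split by library: one was 93.8% WT and the other 95.9% µMT, and each was thus largely a library of its own. Other clusters led with interferon response genes (367 cells), memory genes (416 cells) or cycling genes (95 cells); 101 cells led with Hivep3, Tnfrsf9 and Egr3, and 28 shallow cells remained unnamed. Cluster sizes were not compared, because genes that define them differ between the libraries. Within the memory-like cluster 135 genes were higher and 101 lower in µMT. Crip1 was at -1.50 there, Cxcr6 at -1.08, Irs2 at 2.27 and Ly6a at 1.42, and the memory genes Cxcr3 (-0.74), S100a6 (-0.79) and Gzmm (-0.63) were lower, while Eomes was at 0.03 and Il2rb at 0.04.

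TCR variable gene use rested on few UMIs. Of the beta chain genes Trbv12-2 alone had 100 UMIs or more, at 16.1% (13.0 to 19.6%) of 504 UMIs in WT and 21.0% (17.4 to 24.9%) of 477 in µMT. Of 5 alpha chain genes, Trav14d-3-dv8 was 1.52 times as frequent in µMT, at 3.64% in WT and 5.54% in µMT, and the others had ratios of 0.849 to 1.26. The UMIs of 1 cell are not independent, so these intervals are too narrow.

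**Figure D4:**
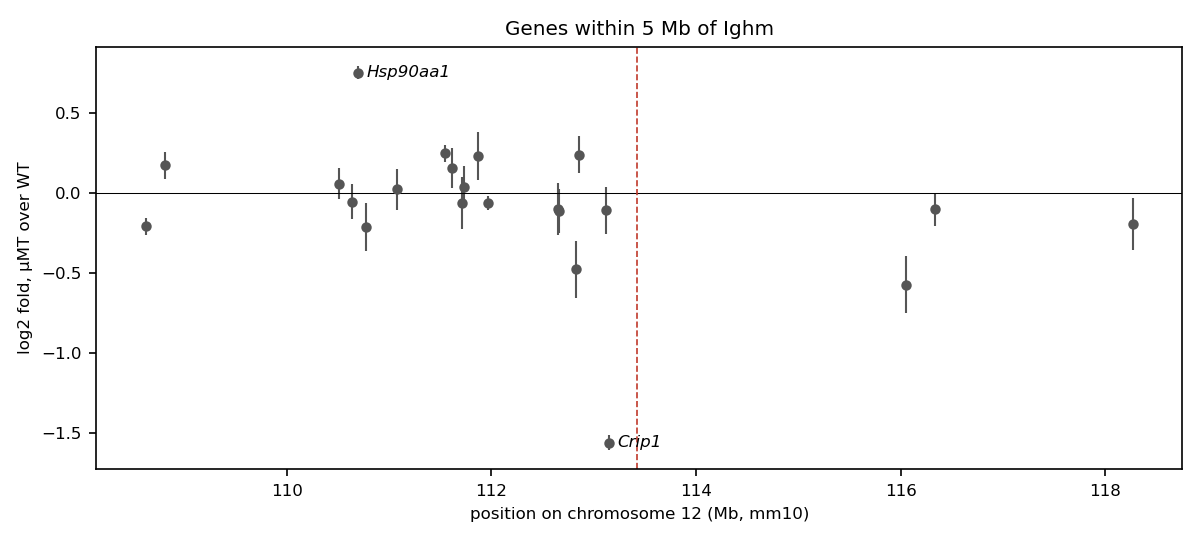
Log2 fold of µMT over WT in all CD8-positive cells (y axis, with 95% counting intervals) of the genes over the minimum within 5 Mb of Ighm, by position on chromosome 12 of mm10 (x axis, Mb; dashed line, Ighm). Crip1, from 113146316 to 113153879, is at -1.56, and Hsp90aa1 is at 0.75.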

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

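The tests of the Sca1 antibody and the immediate-early genes, and the test of Crip1 within a gate, were chosen only after the results were seen; the test of the region around Ighm was chosen before its statistic was computed, although the folds of Crip1 and Hsp90aa1 were already known.

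The tag of Sca1, an antibody in the tables that the labels do not name, was far more abundant in µMT. Its median was 29 tags per cell in WT (quartiles 11 and 99) and 252 in µMT (quartiles 68 and 653), a ratio of 8.69, and in 79.5% of pairs of 1 WT and 1 µMT cell the µMT cell was higher. Ly6a mRNA (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031) was at 32.6 CPM in WT and 57.7 CPM in µMT.

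A deeper antibody library or more staining overall is argued against by the other antibodies, whose larger median ratio was 1.05. Stronger staining by the Sca1 antibody alone cannot be told apart from more protein. At the same number of Sca1 tags the median log2 fold of Ly6a mRNA was -0.93. However, tags rose more than mRNA, so a lower value was given in advance whatever the cause. The rises are unlike measures: 8.69-fold for the median of tags per cell and 1.77-fold for the CPM of summed cells. Summed over cells, Sca1 tags were 249260 in WT and 1165401 in µMT, a smaller rise than that of the median. A type I interferon response across all cells had its list at percentile 53.7. In thinned cells the quartiles of interferon list UMIs were 18 to 33 in WT and 16 to 31 in µMT. These quartiles argue against a rise in most cells. A response in part of the cells stays open: 6.58% of µMT and 4.85% of WT cells lay above the WT 95th percentile. The list was at percentile 99.97 in both CD62Llow gates. Its median was 0.18 (0.05 to 0.33) in CD44low CD62Llow cells. In CD44high CD62Llow cells it was 0.13 (-0.008 to 0.26), an interval that includes no change, and 33 of 36 genes were not called. Random lists in that gate lay from -0.30 to 0.03, so its percentile partly reflects the lower folds of other genes. A difference in Ly6a translation between genotypes stays open too and was not tested. The higher Ly6a mRNA in µMT is not accounted for by staining.

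Crip1 lies near the targeted Ighm gene (at -270.5 kb from its midpoint) and was lower in every gate. Fewer memory-phenotype cells in µMT would leave naive cells alike, but the log2 fold within CD44low CD62Lhigh cells was -1.58. DNA of the embryonic stem cells around the targeted gene, which may differ from C57BL/6, could not be excluded: the 21 other genes within 5 Mb had a median absolute log2 fold at percentile 70.3 of 4320 windows of as many genes, and 4.76% of them were called, against 3.06% elsewhere (percentile 51.5). A few differing alleles would not move a median, so Crip1 regulation in µMT and a linked allele cannot be told apart here.

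The median of the immediate-early list was higher in µMT in every gate, although 2 of its genes were lower in CD44high CD62Llow cells. Different gate shares are argued against, since the list median was 0.78 after the shares were set equal. A small subset of strongly activated cells is argued against too, since the lower quartile of thinned µMT cells, 35.25 UMIs, lay above the upper quartile of WT, 34. Stress of cell preparation may account for it, as the heat shock list was at percentile 100 in all cells. The immediate-early median was highest, at 0.98, in CD44high CD62Llow cells. There the heat shock list was at 0.12 (percentile 95.9), inside the range of random lists, although 2 of its 10 genes were higher and 0 lower. The cells of this gate were of mixed kinds, which bears on both lists. Each genotype was prepared as 1 library, so preparation and genotype are confounded, and an effect of the missing B cells stays open and untested.

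In different gates, 4 genes were called in opposite directions, 2 of them among the named genes, and the difference between gates was not tested. Cks2 had a log2 fold of -1.35 in CD44high CD62Llow cells, with 54.7% of its UMIs in 1 cell, and of 1.31 in CD44low CD62Lhigh cells. Xcl1 had a log2 fold of -3.53 in CD44high CD62Llow cells and 4.0 in CD44low CD62Llow cells, with 66.7% and 100% of its UMIs in 1 cell. The others, named after their values were seen, had at most 12.5% of their UMIs in 1 cell: Sox4 was at -1.62 in CD44high CD62Llow, 0.75 in CD44low CD62Lhigh and 0.60 in CD44high CD62Lhigh cells, and Mrpl49 at -1.06 in CD44high CD62Llow and 1.43 in CD44low CD62Llow cells.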

How the results depend on the processing

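No paired analysis was possible because each genotype had 1 library. The CD44 threshold of 1000 tags and the removal of cells under 3000 UMIs and of genes with over 25% of their UMIs in 1 cell were chosen only after the results were seen. Gate shares kept their direction with thresholds 0.1 higher or lower, without the CD8 gate, without doublets and without cells under 3000 UMIs. Scrublet called 79 WT (3.59%) and 3 µMT cells (0.122%) doublets, so this removal tests little in µMT. The WT CD44low CD62Llow gate was the shallowest, at a median of 3138.5 UMIs, and the WT CD44high CD62Llow gate the smallest, at 63 cells. Where no reason is given below, the cause was not tested.

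Thresholds from pooled cells gave share differences of -2.84 points for CD44low CD62Lhigh and -1.25 for CD44high CD62Lhigh, and aligned peaks gave -0.779 and -4.06. Using 1 threshold moves cells between CD44low and CD44high in both libraries by construction. The CD44 threshold of 1000 tags gave 0.457 points for CD44high CD62Llow and 3.52 for CD44low CD62Llow, 207 genes apart in CD44low CD62Llow, and 1 gene higher and 0 lower in CD44low CD62Llow cells of both libraries. Its CD44high CD62Llow gate held 17 WT cells, so its genes were not compared.

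At least 1000 genes and at most 5% mitochondrial UMIs left 253 WT and 406 µMT cells. Share differences were -2.48 points for CD44low CD62Lhigh, -1.27 for CD44low CD62Llow and -1.16 for CD44high CD62Llow, the last 2 of the other sign; 131 genes were higher and 131 lower in all cells, and 259 were apart in CD44high CD62Lhigh. The CD62Llow gates had under 50 cells, so their gene comparisons have no value.

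In the comparison of CD44low CD62Llow with CD44low CD62Lhigh cells, TMM scaling within each library gave 0 genes higher in both libraries. In all CD8-positive cells it raised every fold of µMT over WT by the same amount and gave 21 lower genes. List medians of the other sign were 0.0254 for interferon response, 0.0590 for mitochondrially encoded, 0.0297 for gut homing and 0.0673 for naive genes. Medians that kept their sign included -0.0483 for cell cycle, -0.0566 for costimulation, TCR complex and CD8, 0.14 for ribosomal proteins, -0.0873 for cytotoxic and -0.0379 for glycolysis genes. They also included 0.49 for heat shock, 0.87 for immediate-early, 0.12 for memory, -0.0419 for nuclear oxidative phosphorylation and -0.0163 for oxidative stress defence genes. Totals without mitochondrial and ribosomal protein genes gave 166 higher and 58 lower genes, 315 apart in CD44low CD62Lhigh and 277 in CD44high CD62Lhigh.

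A 2-fold rule, which is stricter by construction, gave 40 higher and 3 lower genes, 45, 75, 41 and 172 genes apart in CD44low CD62Lhigh, CD44low CD62Llow, CD44high CD62Lhigh and CD44high CD62Llow, and 0 higher and 1 lower gene in CD44low CD62Llow cells of both libraries. A minimum of 50 CPM, which tests fewer genes, gave 57 higher and 18 lower genes, 85 apart in CD44low CD62Lhigh and 77 in CD44high CD62Lhigh, 1 higher and 0 lower gene in CD44low CD62Llow cells of both libraries, and list medians of 0.16 for gut homing and -0.16 for survival; the inhibitory receptor list had no value. No CPM minimum gave 314 higher and 319 lower genes, 473 apart in CD44low CD62Lhigh and 555 in CD44high CD62Lhigh. Equal weight for each cell gave 621 genes apart in CD44low CD62Llow and 59 higher in CD44low CD62Llow cells of both libraries. The weighted sums were treated as counts, so a UMI of a shallow cell counted several times and the intervals were too narrow. These numbers of genes are therefore too high to be read as a dependence on the weighting. Leaving out cells within 0.1 of a threshold gave 1 gene lower in both libraries.

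Of the 29 genes followed in all cells, 19 moved outside their interval under the filter of 1000 genes and 5% mitochondrial UMIs, and 0 reversed. The sizes of the folds given above thus depend on this filter. With gate shares set equal, 110 of the 110 higher and 36 of the 37 lower genes were shared. The number of clusters was 6 at resolution 0.4 and 10 at resolution 1.0.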

Other observations

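Sca1 tags and the interferon response went together within each library, in a comparison chosen only after the data were seen. Cells above the library's median of Sca1 tags had 11.2 times the Ly6a mRNA of the other cells in WT and 7.36 times in µMT. Their interferon list median was 0.18 higher in WT and 0.31 higher in µMT on the log2 scale, both at percentile 100. In µMT Ifit3 (0.74) and Ifit1 (0.70) were higher in these cells, while Ifit1 was at -0.01 in WT. Fos and Crip1 differed little with Sca1 in either library: Fos was at -0.07 and 0.02, and Crip1 at 0.06 and -0.04.

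In cells thinned to 7224 UMIs, 38.7% of µMT cells (36.6 to 40.8%) held more immediate-early UMIs than the 95th percentile of WT cells, against 4.95% of WT cells. For the memory list it was 1.82% (1.30 to 2.48%) against 4.85%, largely through Crip1: without this gene it was 3.64% (2.89 to 4.52%) against 5.01%, and the median numbers of UMIs were 13 in WT and 12 in µMT. With all members they were 17 and 14. For the interferon list the share was 6.58% (5.57 to 7.72%) against 4.85%. The median numbers of naive list UMIs were 37 in WT and 41 in µMT, and those of the interferon list 24 and 22. Before thinning these medians were 56 and 60, and 38 and 32.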
